A study of Homo sapiens with 12 samples.

How the data were processed

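Gene expression was measured in WS1 human skin fibroblasts on 12 single-channel oligonucleotide arrays. The groups follow the sample titles: control at 6 and 24 h and low dose UV-C at 6, 12, 18 and 24 h, with 2 arrays each. The values used are the deposited intensity values, 1 linear signal per probe set and array, for 12625 probe sets of which 67 are AFFX controls. How the authors computed these signals from the scans, and with which software, is not given in the sources used here. The trimmed mean signal, with 2% of the values left out at each end, was 100 on every deposited array to within rounding, which is what global scaling to a common target leaves, so no further scaling was applied and an alternative without scaling is identical to the setting used. Scaling of this kind fixes the average of each array, so that a shift of all transcripts in one direction is not visible.

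Signals were raised to a floor of 20, which is 0.2 of the common trimmed mean, and taken to log2. Control probe sets and those that did not reach a signal of 50 on at least 2 arrays were left out, and 6268 probe sets remained. A change against a group at the floor on all its arrays is a lower bound and is given as at least that fold. Gene symbols came from the platform annotation, in which 10961 probe sets have 1 symbol, 545 several and 1119 none. Of the probe sets with 1 symbol, 10949 matched the GRCh38.p14 gene table through their Entrez numbers, and 0 symbols changed. Genes were named only from probe sets with 1 symbol, 5551 of those kept, and for 4623 genes the probe set with the highest mean log2 signal stood for the gene in the lists. Where another probe set of a named gene moved the other way or differed by more than 1 on the log2 scale in the comparison fitted to all arrays, its value is given.

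Comparisons were fitted with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend on all 12 arrays in 6 groups, which leaves 6 residual degrees of freedom. Irradiated arrays were compared with controls of the same time at 6 and 24 h. At 12 and 18 h, which have no controls of their own, they were compared with the mean of both control times. Also fitted were the difference between the 24 h and 6 h effects, the difference between the control times, and, as 2 groups with 10 residual degrees of freedom, 8 irradiated against 4 control arrays. Adjusted p-values are Benjamini-Hochberg values over the 6268 probe sets with a threshold of 0.05. The median standard error of a log2 change was 0.43 at 6 and 24 h, 0.37 at 12 and 18 h, and 0.25 over all times, which sets the size of change that the arrays can resolve.

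The 22 gene lists hold 643 genes, 375 of them measured, and were fixed before the data were examined, as were the comparisons. They cover p53 targets, G2/M and mitosis, G1/S and DNA replication, nucleotide excision repair, recombination and checkpoint, immediate early and AP-1 genes, NF-kB and inflammatory genes, the interferon response, collagens and matrix, metalloproteinases and inhibitors, TGF-beta and serum response, apoptosis, oxidative stress and NRF2, heat shock, unfolded protein and amino acid stress, cholesterol synthesis, ribosomal proteins, replication-dependent histones, and markers of keratinocytes, melanocytes, endothelial cells and leukocytes. Each list was tested against the other genes with camera in limma, two-sided, at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. None of the list calls held when the correlation was estimated per list, nor with the rotation test fry, which asks whether the genes of a list move one way on balance. Members were also counted after adjustment over the list alone. Medians per array were compared by an exact permutation test for the lists with enough members.

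The genes named for each comparison are those past the threshold whose irradiated arrays all lie on one side of the controls, up to 10 in each direction, and, where fewer than 5 pass, the 5 with the smallest p, stated as not passing. For the difference between effects and between control times the rule asks for the 5 largest of each direction. From each list up to 3 members with the smallest p were eligible, passing or not, and members called over the list alone were named with their counts.

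The steps were tested on simulated data. The noise was normal, independent between genes and of the size seen within groups, without a floor, differences between times or a batch. The shares called may therefore be higher than on the real arrays, above all in the fit over all times. With 100 probe sets changed by 1 on the log2 scale, 13% were called in the 6 h comparison, 16% at 12 h and 62% over all times. With a change of 2 these shares were 61%, 75% and 93%. Of 6047 unchanged probe sets, 2, 10 and 11 were called.

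The alternatives were quantile normalization, centring of each array on its median, floors at 0.05 and 0.5 of the trimmed mean, no filter, a stricter filter on mean signal, no intensity trend, an added minimum change of 1 on the log2 scale, the replicate number as a block, fits with only the arrays compared, other choices of controls, and each array left out in turn. For single probe sets these were planned, and leaving out both 24 h arrays of replicate 2 was added after the data were seen. For the gene lists, an estimated correlation, fry, quantile normalization, no filter and the replicate block were planned, and all other settings, the arrays left out and the exact permutation test were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.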

Results

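WS1 is a human skin fibroblast line that stops dividing after a limited number of passages. Its response to a low dose of UV-C, short-wave ultraviolet light that damages DNA directly, was measured as total RNA hybridised to oligonucleotide expression arrays with 12625 probe sets. Irradiated cells were collected at 6, 12, 18 and 24 h and untreated cells at 6 and 24 h, with 2 arrays in each of the 6 groups. The dose itself is not given in the sources used here. The labels number the replicates 1 and 2 but do not state that they came from separate cultures. The p-values of single probe sets therefore measure the spread between these arrays, which may be technical. The list test at the preset correlation compares the members with the other genes and takes genes as nearly independent. Its p-values therefore rest on the number of genes and do not measure the spread between arrays alone. The 12 arrays had been brought to a common trimmed mean signal of 100, and between 37.1% and 42.3% of the probe sets on an array reached a signal of 50. No array had its labelled replicate as its nearest neighbour, and the median Pearson correlation across probe sets was 0.920 within groups and 0.918 between groups. The precision of each group is limited by its 2 arrays.

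At 6 h the irradiated cells held more RNA of genes that the tumour suppressor p53 switches on after DNA damage. CDKN1A, which encodes the p21 inhibitor of cyclin-dependent kinases, was 4.05-fold higher than in the 6 h controls (log2 change 2.02, SE 0.47), with signals of 1511 and 2429 against 469 and 476. GDF15, a secreted stress cytokine, was 5.51-fold higher (log2 change 2.46, SE 0.72) and PLK2, a polo-like kinase, 3.46-fold higher (log2 change 1.79, SE 0.46). Of the 22 measured genes among 42 listed p53 targets, 21 had a change above 0 and the median log2 change was 0.94. Adjusted over the list alone, 9 of them rose: CDKN1A, GDF15, PLK2, TNFRSF10B, PMAIP1, GADD45A, EPHA2, BTG1 and TRIAP1. The death receptor gene TNFRSF10B changed by 1.17 (SE 0.43) and PMAIP1, a pro-apoptotic member of the BCL2 family, by 1.59 (SE 0.61). As a list the p53 targets moved above the other genes with an adjusted p of 4.30e-10 at the preset correlation of 0.01 between genes, and with an adjusted p = 0.451 with an estimated correlation. The change held in both replicate numbers, with list medians of 0.61 in replicate 1 and 1.14 in replicate 2. Against all 4 controls the median was 0.62 (adjusted p 3.97e-07).

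**Figure D1:**
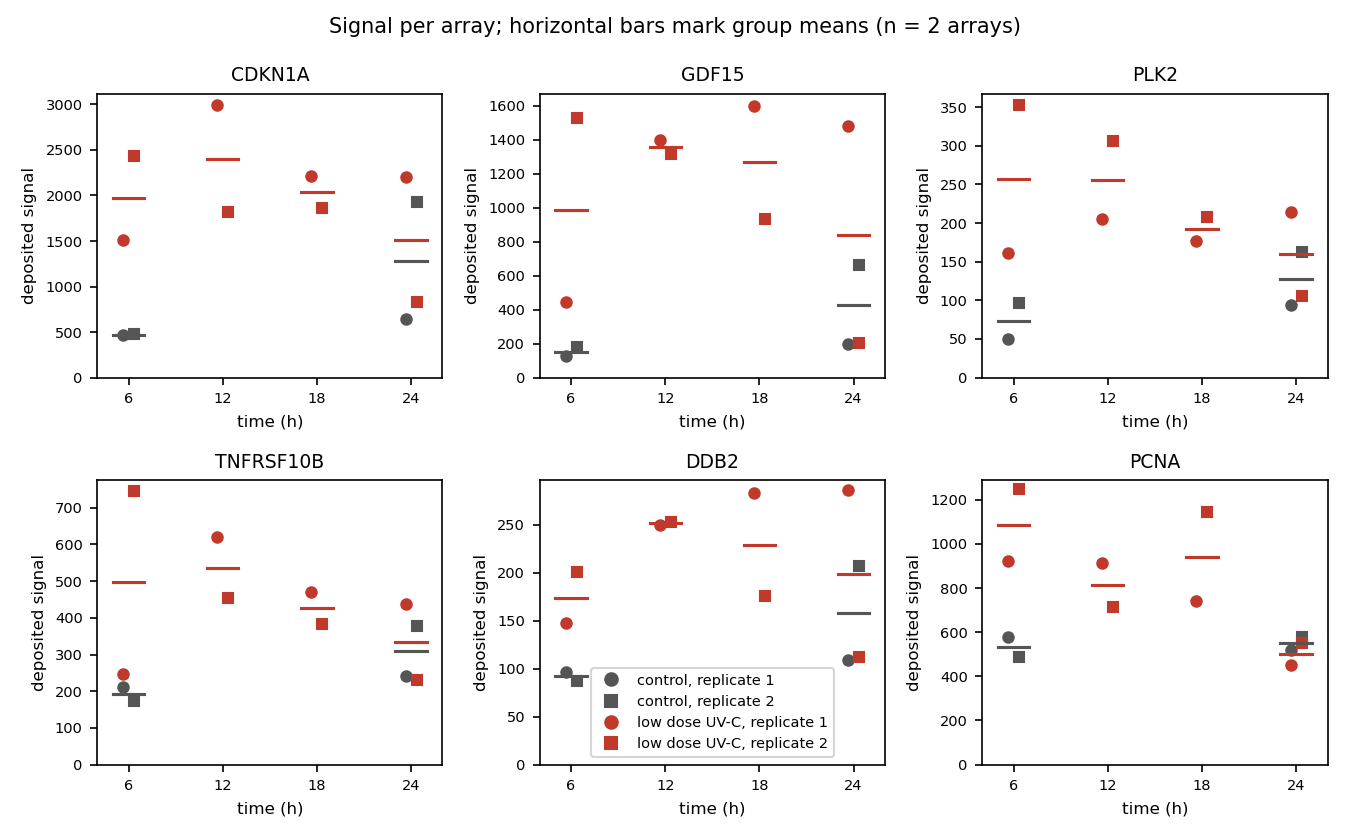
Deposited signal (vertical axis, linear) of 6 genes on each array against time in hours. Circles are replicate 1, squares replicate 2, grey control, red low dose UV-C, and horizontal bars group means of 2 arrays. For CDKN1A both irradiated arrays at 6 h, at 1511 and 2429, lie above both 6 h controls, while at 24 h the control array of replicate 2, at 1929, lies above the irradiated array of replicate 2, at 825.

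The ribosomal protein genes showed a small and even shift at 6 h. All 46 measured members had a change above 0, with a median log2 change of 0.24 (adjusted p 4.92e-05 at the preset correlation, adjusted p = 0.685 with an estimated correlation), and RPL35 had a change of 0.48 (SE 0.24). The median was 0.15 after quantile normalization (adjusted p 0.0160) and without the 6 h control of replicate 2 (0.0443). Over the 12 arrays this list median tended to be higher where the array's median signal was lower. Relative to the 6 h controls it was highest (0.44) at the lowest median signal, 27.8 (irradiated 12 h, replicate 1). It was lowest (-0.26) at the highest median signal, 35.9 (24 h control, replicate 2). The order was not strict, with -0.11 at 32 (irradiated 12 h, replicate 2). Signal distribution and irradiation were therefore not separated for this list. Genes of G2/M and mitosis had a median of -0.21, with 7 of 30 above 0 (adjusted p 0.0833). PLK1, a kinase of mitotic entry, had a change of -1.04 (SE 0.36), AURKA one of -0.75 (SE 0.32) and the spindle motor gene KIF11 one of -0.91 (SE 0.40). The list of 20 TGF-beta and serum response genes had a median of -0.24 (adjusted p 0.0592). Within it TGFBR2, the type II TGF-beta receptor, fell by 1.57 (SE 0.42) when adjusted over the list alone, while ID1 and ID3, inhibitors of basic helix-loop-helix factors, had values of -0.96 (SE 0.39) and -0.69 (SE 0.24). Both lists passed after quantile normalization (adjusted p 0.0160 for G2/M and mitosis, 0.00522 for TGF-beta and serum response), without a filter (0.0109 each) and with the stricter filter (0.00917 and 0.00186). The same held without the 6 h control of replicate 1 (medians -0.45 and -0.43, adjusted p 0.00494 and 0.0254). G2/M also passed without the irradiated array of replicate 2 (-0.39, 0.00954), as did keratinocyte markers (0.75 where the median over all arrays was 0.19, 0.0119), and TGF-beta with the lower and the higher floor (0.0453 and 0.00885). Against all 4 controls the G2/M median was 0.09, turned in direction (0.846). All 13 heat shock genes lay above 0 with a median of 0.22 and an adjusted p of 0.0674. It was 0.0383 with the higher floor and 0.00365 without a filter. Without the irradiated array of replicate 1 the median was 0.37. With the replicate number as a block, G2/M, TGF-beta and heat shock genes all passed (adjusted p 0.0486 each).

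No list of DNA synthesis or repair genes passed at 6 h. PCNA, the sliding clamp of DNA polymerases, had a change of 1.01 (SE 0.27) and CCNE1, the cyclin of S phase entry, one of 1.94 (SE 0.56) with 1 control array at the floor. PRIM2, a primase subunit, stood at -1.68 (SE 0.57). The 33 G1/S and DNA replication genes had a median of 0.01 (adjusted p 0.650). Among 20 nucleotide excision repair genes, which remove UV photoproducts, the median was 0.03 (adjusted p 0.892). MNAT1, a subunit of the TFIIH kinase, stood at -1.78 (SE 0.62), RAD23B at -0.71 (SE 0.30) and the damage sensor DDB2 at 0.90 (SE 0.43). The 18 immediate early and AP-1 genes had a median of 0.12 (adjusted p 0.472), with JUNB at 1.62 (SE 0.66), DUSP1 at -0.70 (SE 0.27) and KLF6 at -0.76 (SE 0.30). The 13 NF-kB and inflammatory genes had a median of -0.27 (adjusted p 0.892), with NFKB1 at -1.22 (SE 0.41) on its brightest probe set, 0.05 and -1.15 on the others, and the pentraxin gene PTX3 at -1.21 (SE 0.48).

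Over all 6268 probe sets tested, limma called 0 at 6 h, the smallest adjusted p being 0.560, and 423 had an unadjusted p under 0.05 where 313.4 would by chance, 148 higher and 275 lower. The 5 named genes with the smallest p therefore did not pass the test. These were PAFAH1B1, a dynein regulator (-1.87, SE 0.40), TPST1, a tyrosylprotein sulfotransferase at the floor on both irradiated arrays and so at least 4.69-fold lower, the phosphate transporter SLC20A2 (-1.52, SE 0.34), CDKN1A and the chemokine CXCL12 (-1.71, SE 0.40). A dimmer probe set of PAFAH1B1 gave 0.29, and a second probe set of CXCL12 gave -0.38. Centring each array on its median raised all changes by 0.21 at 6 h, 0.22 at 12 h, 0.10 at 18 h, 0.16 at 24 h and 0.17 over all times, so the sign of a small negative median depends on the zero chosen. The list calls of the irradiated against the control arrays, which rest on a comparison with the other genes, were all kept after that centring.

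At 12 h p53 targets were higher than in the 4 control arrays of 6 and 24 h, there being no 12 h control in the design. GDF15 was 5.82-fold higher (log2 change 2.54, SE 0.63), CDKN1A 3.22-fold higher (1.69, SE 0.40) and PLK2 2.72-fold higher (1.44, SE 0.40). The median of the 22 p53 targets was 0.91 with 19 above 0, and 7 rose when adjusted over the list alone: CDKN1A, GDF15, PLK2, EPHA2, EI24, TNFRSF10B (1.14, SE 0.38) and DDB2 (1.10, SE 0.37). The list had an adjusted p of 3.81e-08 at the preset correlation and an adjusted p = 0.551 with an estimated correlation. The 12 h and 18 h comparisons share their 4 control arrays.

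All 13 heat shock genes had a change above 0 at 12 h, with a median of 0.33 (adjusted p 0.0112, adjusted p = 0.551 with an estimated correlation), and the co-chaperone gene DNAJA1 stood at 0.75 (SE 0.26). That call was lost against the 24 h controls alone (median 0.26, adjusted p 0.146), with a stricter filter on dim probe sets (0.31, 0.0865) and without the 12 h array of replicate 1 (0.23, 0.0765). Ribosomal protein genes had a median of 0.23, with 45 of 46 above 0 (adjusted p 3.77e-05, adjusted p = 0.769 with an estimated correlation), but without the 12 h array of replicate 1 the median was -0.06 (adjusted p 0.622), without that of replicate 2 it was 0.52 (6.78e-12), and after quantile normalization 0.15 (0.00984). TGF-beta and serum response genes had a median of -0.26 (adjusted p 0.107) and collagens and matrix one of -0.11, neither passing. Both passed after quantile normalization (0.0172 and 0.0281), with the stricter filter (0.0136 each), and against the 6 h controls alone (0.0134, at a TGF-beta median of -0.43, and 0.0400). They also passed without the 12 h array of replicate 1 (medians -0.16 and -0.17, adjusted p 0.0314 each). Interferon response and apoptosis genes, each with a median of 0.27, passed after quantile normalization (0.0365 and 0.0407) and without the 24 h control of replicate 2 (0.0397 each), and interferon genes also against the 6 h controls (median 0.58, 0.00411). Calls also appeared for oxidative stress and NRF2 without a filter (0.0470), for unfolded protein and amino acid stress against the 6 h controls (-0.28, with all controls -0.15, 0.0262) and for G2/M and mitosis, higher, against the 24 h controls (0.19, 0.0197), where the median against the 6 h controls was -0.20, not passing. G1/S genes were called lower without the 12 h array of replicate 1 (-0.20, 0.0295) and higher without that of replicate 2 (0.32, 0.0303), the median with both being 0.07. In the fit of all arrays VCL, the focal adhesion protein vinculin, fell by 0.93 (SE 0.25) when adjusted over the list alone, and the actin-binding proteins ACTN1 and CALD1 stood at -0.53 (SE 0.20) and -0.96 (SE 0.37). Other members of fixed lists with small p-values were the securin gene PTTG1 at 1.20 (SE 0.32), GPX1, a glutathione peroxidase, at 0.77 (SE 0.23), PCNA at 0.58 (SE 0.24), the interferon-inducible ISG15 at 0.76 (SE 0.30) and the peptide transporter gene TAP1 at 1.22 (SE 0.51). ATF4, a transcription factor of amino acid stress, stood at -0.69 (SE 0.22) and MNAT1 at -1.64 (SE 0.54).

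For single probe sets at 12 h limma called 0, with a smallest adjusted p of 0.377, and 524 had an unadjusted p under 0.05, 256 higher and 268 lower. The smallest p among named genes, none of which passed, belonged to MICAL2, an actin-oxidising enzyme (-1.36, SE 0.28), the receptor phosphatase PTPRK (-2.31, SE 0.49, 1 irradiated array at the floor), the F-box gene FBXL7 (-1.86, SE 0.41), the centrosomal gene CEP43 (1.79, SE 0.40) and POLR2A, the largest subunit of RNA polymerase II (1.02, SE 0.24). Without the 12 h array of replicate 2, PTPRK was at least 11.3-fold lower, since the 1 irradiated array left lay at the floor.

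At 18 h GDF15 was 5.25-fold higher than in the controls (log2 change 2.39, SE 0.63) and CDKN1A 2.80-fold higher (1.49, SE 0.40). These and EPHA2, an ephrin receptor (0.96, SE 0.29), were the 3 p53 targets that rose when adjusted over the list alone. The list median was 0.74, with 19 of 22 above 0 and an adjusted p of 2.29e-08 at the preset correlation, adjusted p = 0.303 with an estimated correlation. The arrays did not separate fully. Relative to the 6 h controls, both 18 h arrays had list medians (0.91 and 0.89) below that of the 24 h control of replicate 2 (0.95). DDB2 stood at 0.92 (SE 0.37) and PCNA at 0.77 (SE 0.24), whereas RRM2, a subunit of ribonucleotide reductase, was 2.01-fold lower and the thymidine kinase gene TK1 stood at -0.68 (SE 0.26), where its other probe set gave -0.02.

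Ribosomal protein genes had a median of 0.14 at 18 h, with 42 of 46 above 0 (adjusted p 0.0207, adjusted p = 0.825 with an estimated correlation). That call was lost after quantile normalization (median 0.11, adjusted p 0.0748), against the 6 h controls alone (0.08, 0.282) and when the 6 h control of replicate 2 (0.09, 0.150), the 24 h control of replicate 2 (0.08, 0.239) or the 18 h array of replicate 2 (0.11, 0.242) was left out. It grew against the 24 h controls alone (0.21, 7.88e-04) and without the 24 h control of replicate 1 (0.22, 0.00132). G2/M and mitosis genes had a median of -0.22 (adjusted p 0.137) and TGF-beta and serum response genes one of -0.20, neither passing. Both passed without a filter (0.0378 and 0.0292), against the 6 h controls alone (medians -0.47 and -0.33, adjusted p 7.18e-05 and 0.0114), without the 6 h control of replicate 1 (0.0314, at a G2/M median of -0.35, and 0.0386) and without the 18 h array of replicate 2 (0.00910 each). TGF-beta also passed after quantile normalization (0.0244) and with the stricter filter (0.0365). Against the 24 h controls alone the G2/M median was 0.06 (0.537), and without the 18 h array of replicate 1 it was -0.10 while the list test pointed up (0.951). Without the 18 h array of replicate 2, calls also appeared for interferon response (0.39, 0.0116, and 0.30, 0.0286 against the 6 h controls), collagens (-0.29, 0.00476) and unfolded protein stress (-0.26, 0.0135). With all arrays these medians were 0.16, -0.14 and 0.03. Without the 18 h array of replicate 1 they turned for interferon response (-0.17, 0.873) and collagens (0.11, 0.580) and that of unfolded protein stress was 0.25 (0.0960). Immediate early genes had a median of 0.17 (adjusted p 0.0770), with the orphan nuclear receptor NR4A1 at 1.30 (SE 0.52) against 3 of 4 controls at the floor. The cytokine gene IL11 stood at 1.10 (SE 0.39). SOX10, the 1 melanocyte marker measured, rose by 1.20 (SE 0.51) when adjusted over the list alone, which for a single gene is no adjustment, and 1 control array lay at the floor. The list test of that gene passed with the higher floor (0.62, 0.00343) and without the 6 h control of replicate 1 (0.0386). The log2 ratio of 3' to 5' signal, a sign of RNA quality, was higher in the irradiated 18 h arrays by 0.31 for GAPDH and 0.36 for actin, with within-group SDs of 0.11 and 0.21, and at 24 h by 0.24 and 0.12.

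Over all probe sets limma called 0 at 18 h, and 292 had an unadjusted p under 0.05, 103 higher and 189 lower. The smallest adjusted p, 0.0669, belonged to a probe set without a gene symbol. Named genes with the smallest p, none passing, were LAS1L, a factor of ribosome assembly at the floor on both irradiated arrays and so at least 4.11-fold lower, NCDN (1.02, SE 0.23), POLR2A (0.99, SE 0.24), CXCL12 (-1.40, SE 0.35) and the homeobox gene MEIS2 (-2.19, SE 0.56, 1 irradiated array at the floor). Without the 18 h array of replicate 1, 3 probe sets were called, those of TMEM259, COL6A1 and THBS1, which were chosen for mention after their values were seen. With all arrays that probe set of COL6A1 gave -1.63 and its brightest one 0.30.

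At 24 h the p53 target list was not called between irradiated and control arrays. The list median was 0.06, with 12 of 22 above 0 (adjusted p 0.712), and CDKN1A, named here after its values were seen, had a change of 0.28 (SE 0.47). The 2 replicate numbers pointed in opposite directions. In replicate 1 the list median was 0.83, with 18 of 22 above 0, and CDKN1A stood at 1.78. In replicate 2 it was -0.59, with 4 of 22 above 0, and CDKN1A stood at -1.22. The list median and adjusted p were 0.57 and 0.00723 without the irradiated array of replicate 2, 0.83 and 5.21e-05 without both replicate 2 arrays and 0.33 and 0.0222 against all 4 controls, and the direction turned without the control of replicate 1 (-0.24, adjusted p 0.533) or the irradiated array of replicate 1 (-0.36, 0.203).

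**Figure D2:**
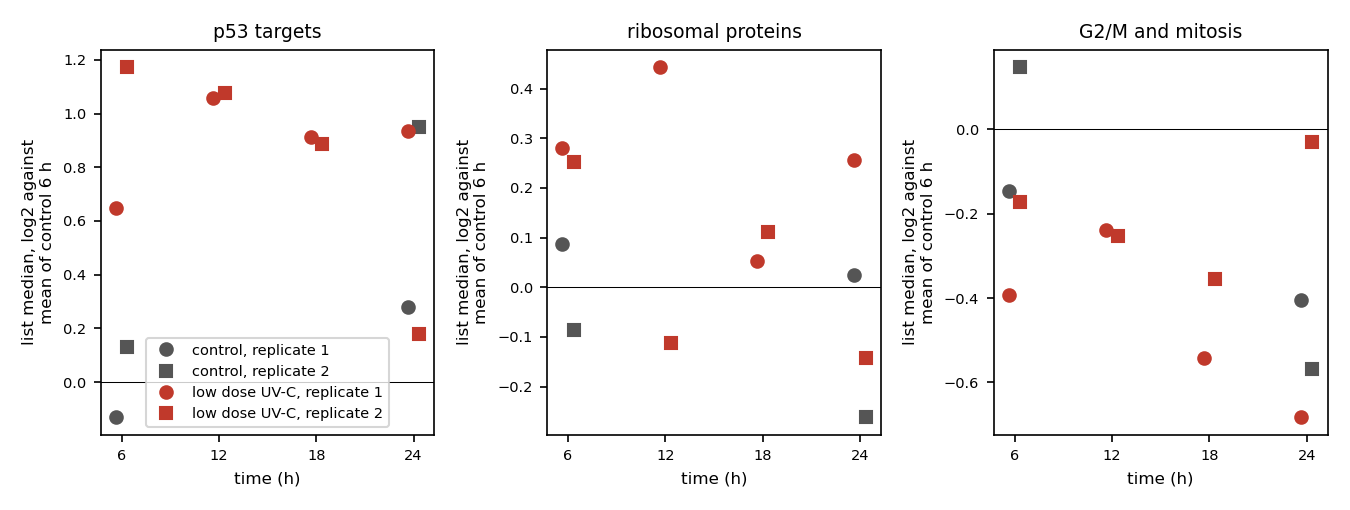
Median log2 signal of 3 gene lists on each array, relative to the mean of the 6 h controls (vertical axis), against time in hours, with circles for replicate 1, squares for replicate 2, grey for control and red for low dose UV-C. For the p53 targets the 24 h control of replicate 2 lies at 0.95 and the 24 h irradiated array of replicate 2 at 0.18.

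Ribosomal protein genes were again slightly higher at 24 h, with a median of 0.17 and 45 of 46 above 0 (adjusted p 5.24e-04, adjusted p = 0.941 with an estimated correlation), where RPL12 stood at 0.47 (SE 0.28). The call was lost after quantile normalization (median 0.05, adjusted p 0.944), without the control of replicate 2 (0.06, 0.717) and without the irradiated array of replicate 1 (0.01, 0.843). It was kept against all 4 controls (0.11, 0.0222) and without the control of replicate 1 (0.31, 3.42e-06) or the irradiated array of replicate 2 (0.36, 3.81e-07). G2/M and mitosis genes had a median of 0.18 (adjusted p 0.0960), with CKS1B, a cyclin-dependent kinase subunit, at 0.93 (SE 0.32) and BIRC5, survivin, at -1.67 (SE 0.61) with 1 irradiated array at the floor, while a dim second probe set of BIRC5 gave 0.10. The list had an adjusted p of 0.0397 without the control of replicate 1 and of 2.10e-08 without the irradiated array of replicate 1, where the median was 0.55. G1/S genes, with a median of 0.05 over all arrays, stood at 0.22 (0.0139) and 0.31 (7.95e-04) in the same runs. The G2/M median turned against all 4 controls (-0.12, 0.838), without the irradiated array of replicate 2 (-0.18, 0.479) and without both replicate 2 arrays (-0.29, 0.322). Without a filter the G2/M list also passed (0.0375), and without both replicate 2 arrays G1/S genes passed as lower (-0.36, 0.0194) and metalloproteinases as higher (0.49, 0.0360), whose median was -0.18 without the control of replicate 1 (0.469). The haem oxygenase gene HMOX1 stood at 1.32 (SE 0.71) and the p53-responsive phosphatase gene PPM1D at 0.60 (SE 0.46). The anti-apoptotic BCL2 stood at -1.24 (SE 0.46) on its brighter probe set and at 1.42 on its dimmer one.

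For single probe sets at 24 h limma called 0 with a smallest adjusted p of 0.971, and 166 had an unadjusted p under 0.05, 53 higher and 113 lower. The 5 named genes with the smallest p did not pass: the mitochondrial tyrosyl-tRNA synthetase gene YARS2 (-1.96, SE 0.41), COL11A2 (-2.26, SE 0.51, with -0.43 on a dimmer probe set), the leukotriene C4 synthase gene LTC4S (-1.96, SE 0.45), the BMP receptor gene ACVRL1 (-2.01, SE 0.49) and GRIK5 (at least 4.50-fold higher, both controls at the floor), whose brighter probe set gave -0.05. Without the irradiated array of replicate 2, BIRC5 was at least 8.15-fold lower, since the 1 irradiated array left lay at the floor. DYNC1LI2, chosen for mention after its values were seen, was also lower in that run.

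Taking the 8 irradiated and 4 control arrays as 2 groups, GDF15 was higher by 2.00 on the log2 scale (SE 0.49), CDKN1A 2.58-fold higher (1.37, SE 0.33) and PLK2 2.21-fold higher (1.15, SE 0.30). The p53 target list had a median of 0.69 with 19 of 22 above 0, and 9 members rose when adjusted over the list alone, DDB2 (0.80, SE 0.27) among them. Its adjusted p was 4.17e-09 at the preset correlation and adjusted p = 0.476 with an estimated correlation. On the level of arrays the list median was 0.86 ± 0.32 (SD, n = 8) in irradiated and 0.31 ± 0.46 (SD, n = 4) in control arrays, and a two-sided exact permutation test over 495 splits gave p = 0.0343, adjusted 0.384 over the lists with at least 4 measured members. The smallest p this test allows is 0.00202. The two-sided exact permutation test gave p = 0.0384 for immediate early and AP-1 genes, with the same adjusted value of 0.384. For that list 5 of 8 irradiated arrays lay above all controls, and for p53 targets 3 of 8. The p53 targets were therefore not singled out by this test.

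Ribosomal protein genes had a median of 0.22 over all times, all 46 above 0 (adjusted p 8.17e-09, adjusted p = 0.740 with an estimated correlation; RPS19 0.39, SE 0.16, RPL12 0.38, SE 0.15, RPL35 0.37, SE 0.14). After quantile normalization the median was 0.12 (adjusted p 8.00e-04) and without the 24 h control of replicate 2 it was 0.14 (4.36e-04). On the level of arrays the two-sided exact permutation test gave p = 0.115 for ribosomal proteins, adjusted 0.533, with 5 of 8 irradiated arrays above all controls. The tie of this list to the median signal of the arrays, given with the 6 h values, was not separated from irradiation here either. Heat shock genes had a median of 0.17 with an adjusted p of 0.0499, and adjusted p = 0.677 with an estimated correlation. That call was lost after quantile normalization (adjusted p 0.237), with either other floor (0.0648 and 0.0650), with the stricter filter (0.307) and with all 6 groups in the fit (0.0801). It was also lost when any of these arrays was left out: the 6 h controls of replicate 1 (0.140) and 2 (0.212), the irradiated 6 h array of replicate 2 (0.0893), the 12 h arrays of replicate 1 (0.103) and 2 (0.0980), the 18 h array of replicate 1 (0.0724) and the irradiated 24 h array of replicate 1 (0.0650). In these runs the median lay between 0.10 and 0.17. Adjusted over the list alone, the repair genes MNAT1 and RAD23B fell by 1.34 (SE 0.36) and 0.55 (SE 0.16), and GPX1 rose by 0.59 (SE 0.17). The matrix protein gene THBS1 stood at -0.63 (SE 0.20) and KLF6 at -0.49 (SE 0.17).

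The other fixed lists did not pass over all times, but several did in other settings. TGF-beta and serum response passed after quantile normalization (0.00310), with the stricter filter (0.0108), without a filter (0.0278) and without the 24 h control of replicate 2 (0.0437). Collagens passed after quantile normalization (-0.12, 0.0230) and with the stricter filter (0.0490), as did NF-kB genes with that filter (-0.43, 0.0490). Interferon response (0.23, 0.0358) and apoptosis (0.29, 0.0437) passed without the 24 h control of replicate 2. Without both 24 h arrays of replicate 2, G2/M and mitosis (-0.23, 0.0294), interferon response (0.22, 0.0294), apoptosis (0.27, 0.0381) and TGF-beta (0.0483) passed. Without the 6 h control of replicate 2 the G2/M median was 0.10 (0.531). Median log2 changes and adjusted p-values were -0.25 and 0.124 for TGF-beta and serum response, 0.16 and 0.156 for apoptosis, 0.14 and 0.244 for the interferon response, 0.13 and 0.321 for immediate early and AP-1 genes, and 0.03 and 0.631 for oxidative stress and NRF2. They were 0.05 and 0.678 for G1/S and DNA replication, 0.11 and 0.678 for the 6 replication-dependent histones measured, -0.21 and 0.783 for NF-kB and inflammatory genes and 0.02 and 0.893 for nucleotide excision repair. Medians of -0.07 for collagens and matrix (0.631), -0.03 for metalloproteinases and inhibitors (0.943), -0.08 for G2/M and mitosis (0.732), -0.09 for recombination and checkpoint (0.732), -0.10 for cholesterol synthesis (0.858) and -0.06 for unfolded protein and amino acid stress (0.868) lay above 0 after median centring, which raised every change alike by 0.17, and below 0 after quantile normalization. Markers of other skin or blood cells had adjusted p-values of 0.732 (keratinocyte, 7 measured), 0.858 (melanocyte, 1 measured), 0.893 (endothelial, 1 measured) and 0.662 (leukocyte, 4 measured).

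**Figure D3:**
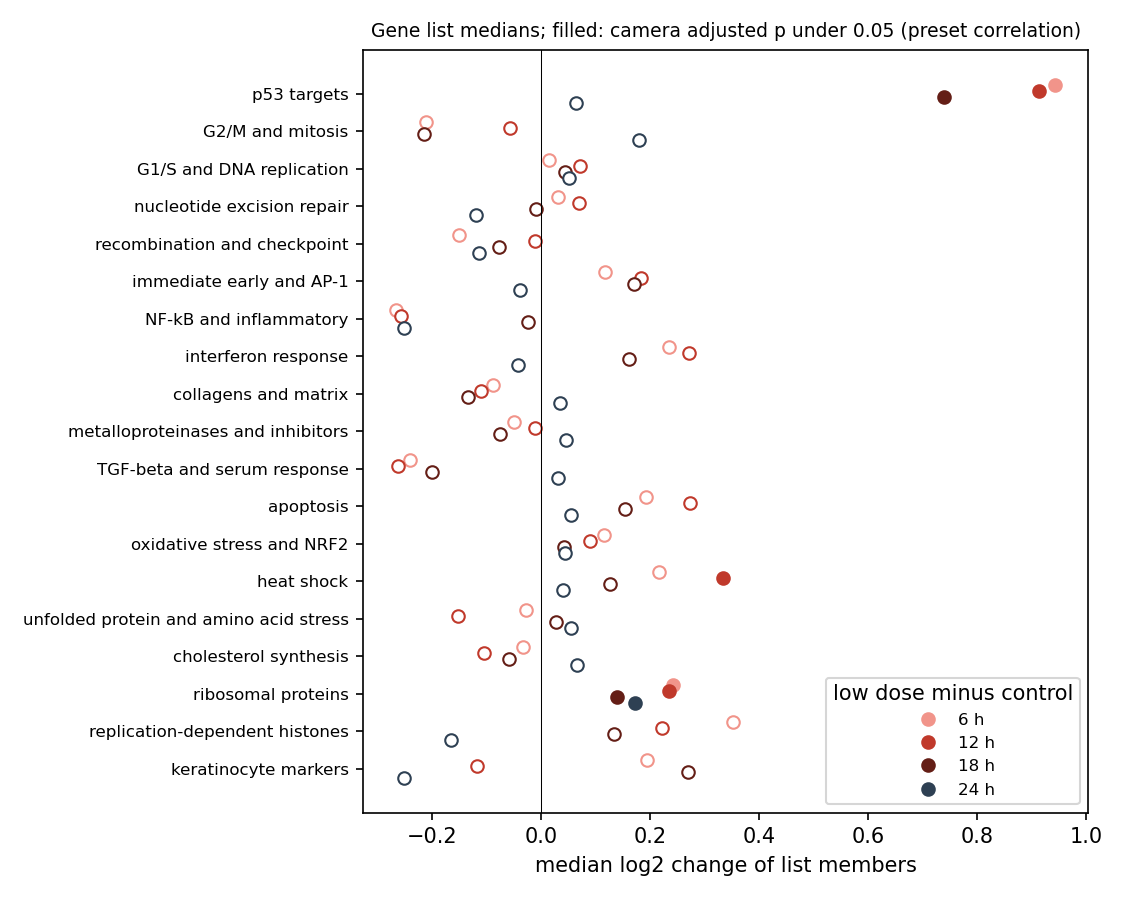
Median log2 change of each gene list with at least 5 measured members (horizontal axis) at 6, 12, 18 and 24 h, with filled symbols where the adjusted p of the list test at the preset correlation was under 0.05. The p53 targets lie at 0.94, 0.91, 0.74 and 0.06, and median centring raises all values of a time alike, by 0.21, 0.22, 0.10 and 0.16.

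Over all times limma called 0 of 6268 probe sets, with a smallest adjusted p of 0.393, and 575 had an unadjusted p under 0.05, 241 higher and 334 lower. The 5 named genes with the smallest p were the kinase gene STK39 (-1.38, SE 0.28), MEIS2 (-1.97, SE 0.41), CEP170B (1.52, SE 0.34, on a dim probe set, with 0.38 on its brightest and -0.05 on its dimmest), CDKN1A and GDF15. Without the irradiated 24 h array of replicate 2, 4 probe sets were called, those of GDF15 (2.31), MEIS2 (-2.19), CXCL12 (-1.30) and SAT1 (1.62), and without the 24 h control of replicate 2 CDKN1A (1.84) was called. With both left out, a choice made after seeing the data, 13 were called, 10 higher and 3 lower, among them CDKN1A (2.01), GDF15 (2.81), PLK2 (1.55) and DDB2 (1.19).

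The effect at 24 h was set against the effect at 6 h to ask whether the response changed with time. CDKN1A had a difference of -1.74 (SE 0.66) and PCNA one of -1.15 (SE 0.39). The p53 targets had a median difference of -0.92, with 3 of 22 above 0 (adjusted p 1.55e-05, adjusted p = 0.707 with an estimated correlation). G2/M and mitosis genes had a median difference of 0.44, with 23 of 30 above 0 (adjusted p 0.00423, adjusted p = 0.707 with an estimated correlation), PLK1 standing at 1.35 (SE 0.50), AURKA at 1.19 (SE 0.45) and BIRC5 at -2.22 (SE 0.86), with 1.01 on its dim second probe set. Both calls rested on the 24 h arrays of replicate 2: without the irradiated one the median was -0.50 for p53 targets (adjusted p 0.194) and 0.19 for G2/M and mitosis (0.810), and without both arrays -0.27 (0.813) and -0.04 (0.990). The p53 call was kept at a median of -0.61 with the higher floor (2.14e-05) and of -0.60 without the irradiated 6 h array of replicate 2 (0.0342). The G2/M call was also lost without the 6 h control of replicate 2 (0.26, 0.381), the 24 h control of replicate 2 (0.35, 0.126) or the irradiated 6 h array of replicate 1 (0.37, 0.171), and grew without the irradiated 24 h array of replicate 1 (0.66, 2.22e-07). TGF-beta and serum response genes were called higher with the higher floor (0.0204), the stricter filter (0.0201) and without the 6 h control of replicate 1 (0.33 against 0.19 with all arrays, 0.0387), the last also for collagens (0.38 against 0.25, 0.0387). Keratinocyte markers (0.0274, without the irradiated 6 h array of replicate 2) and ribosomal proteins (-0.21 against -0.07, 0.0281, without the irradiated 24 h array of replicate 1) were called lower. For single probe sets limma called 0, and 240 had an unadjusted p under 0.05, 106 higher and 134 lower. The 5 named genes with the smallest p did not pass: the elongation factor gene TCEA1 (1.78, SE 0.46), the polymerase delta subunit gene POLD3 (2.40, SE 0.63), RCVRN (-3.00, SE 0.79), C2CD2 (2.30, SE 0.61) and PEA15 (-1.52, SE 0.42).

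In untreated cells the 24 h arrays differed from the 6 h arrays in the genes of cell division. Of 30 G2/M and mitosis genes 2 lay above 0 and the median log2 change was -0.48 (adjusted p 6.37e-08, adjusted p = 0.474 with an estimated correlation). CKS1B stood at -1.07 (SE 0.32), the checkpoint kinase gene BUB1B at -1.51 (SE 0.50) and KIF23, a cytokinesis motor, at -1.80 (SE 0.64) with 1 array at the floor. G1/S and DNA replication genes had a median of -0.27 (adjusted p 0.00332, adjusted p = 0.656 with an estimated correlation), with RFC4 at -1.23 (SE 0.37) and RRM1 at -0.95 (SE 0.35). The p53 targets had a median of 0.63, with 17 of 22 above 0 (adjusted p 0.00332, adjusted p = 0.533 with an estimated correlation), CDKN1A standing at 1.23 (SE 0.47), CCNG1 at 1.16 (SE 0.49) and XPC at 0.78 (SE 0.34). Interferon response genes had a median of 0.43 (adjusted p 0.00942), with TAP1 2.82-fold higher and ISG15 at 0.77 (SE 0.34), and unfolded protein and amino acid stress genes one of -0.39 (adjusted p 0.00332), with the asparagine synthetase gene ASNS at -1.08 (SE 0.49) and PCK2 at -0.96 (SE 0.35). Both had an adjusted p = 0.474 with an estimated correlation. The interferon median was 0.23 with the higher floor (0.00623), 0.17 without a filter (0.00825) and 0.21 without the 6 h control of replicate 2 (0.0160).

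Cholesterol synthesis genes passed with a median of 0.32 (adjusted p 0.0420; INSIG1 1.10, SE 0.56, FASN 0.72, SE 0.35), TGF-beta and serum response genes with -0.18 (0.0420), collagens and matrix with -0.21 (0.0385) and ribosomal proteins with -0.12 (0.0385). With an estimated correlation these had an adjusted p = 0.474, adjusted p = 0.474, adjusted p = 0.533 and adjusted p = 0.889, and after quantile normalization the medians were 0.31 (adjusted p 0.0619), -0.14 (0.156), -0.17 (0.156) and -0.04 (0.762). Median centring also ended the calls for cholesterol synthesis (0.31, 0.0570), TGF-beta (-0.20, 0.0601) and ribosomal proteins (-0.14, 0.0601), with medians close to those above, and leaving out the filter the one for TGF-beta (-0.16, 0.168). Adjusted over the list alone, the cytokine gene IL11 fell by 1.39 (SE 0.45) and PTGS2, cyclooxygenase-2, fell by 1.19 (SE 0.39). Of these 9 list calls between the control times, the G2/M one was kept without each array in turn (adjusted p at most 0.00223). Without the 24 h control of replicate 2 it was the only 1 kept, although not every median shrank. Medians and adjusted p-values were then 0.28 and 0.596 for p53 targets, -0.06 and 0.596 for G1/S and DNA replication, -0.16 and 0.279 for collagens and 0.02 and 0.875 for ribosomal proteins. They were 0.34 and 0.381 for the interferon response, -0.35 and 0.241 for unfolded protein and amino acid stress, -0.30 and 0.241 for TGF-beta, and 0.37 and 0.224 for cholesterol synthesis. Without the 6 h control of replicate 1 they were 0.50 and 0.0951 for p53 targets, -0.26 and 0.0920 for G1/S, 0.46 and 0.0951 for interferon, -0.19 and 0.0763 for TGF-beta, 0.32 and 0.194 for cholesterol and -0.06 and 0.506 for ribosomal proteins. Without the 6 h control of replicate 2 the values were -0.05 and 0.752 for collagens, -0.13 and 0.371 for TGF-beta, -0.27 and 0.108 for unfolded protein stress and 0.22 and 0.108 for cholesterol. Without the 24 h control of replicate 1 they were -0.22 and 0.137 for TGF-beta and 0.19 and 0.194 for cholesterol. Calls appeared for keratinocyte markers without a filter (0.0148) and, lower, for recombination and checkpoint without the 24 h control of replicate 1 (-0.49 against -0.22, 0.0261). Other calls grew: without the 24 h control of replicate 1 the values were -0.55 and 2.52e-06 for G1/S, 0.95 and 6.24e-06 for p53 targets and -0.26 and 4.32e-04 for ribosomal proteins. Collagens stood at -0.38 (0.00356) without the 6 h control of replicate 1, and ribosomal proteins at -0.20 (0.00822) without that of replicate 2. For single probe sets limma called 0, with a smallest adjusted p of 0.996, and 263 had an unadjusted p under 0.05, 153 higher and 110 lower. Of the named genes the smallest p, again without passing, belonged to SPIB (2.08, SE 0.47), RGS9 (at least 4.25-fold lower, both 24 h controls at the floor), the ephrin gene EFNB1 (1.75, SE 0.45), GRIK5 (at least 4.06-fold lower, both 24 h controls at the floor, with 0.09 on its brighter probe set) and MICAL2 (-1.22, SE 0.33).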

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

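The tests of a shared batch and of a single stressed culture were chosen after the result was seen. The test of an exchange was set out before its signature values were seen, but its question came from the p53 target values at 24 h. The p53 target list differed between times by -0.92 in the test of the 24 h effect against the 6 h effect, since at 24 h the irradiated minus control difference was 0.83 in replicate 1 and -0.59 in replicate 2. A batch shared by all replicate 2 arrays would move both 24 h groups one way, but the replicate 2 minus replicate 1 difference was 0.71 in controls and -0.74 in irradiated cells. The SE of the latter, 0.28, covers the genes of the list and not the arrays. The opposite signs argue against such a batch as far as single arrays can. A batch of some arrays stays open, the other groups differing by 0.26 (control 6 h), 0.62, -0.04 and -0.23 (irradiated 6, 12 and 18 h). A stress response of the untreated culture alone is argued against by the irradiated array of replicate 2, whose list median of 0.18 lies below the 0.65 to 1.17 of the other irradiated arrays, though together with a recovery of the irradiated cells by 24 h it stays open and was not tested. An exchange of the 2 arrays may account for both. The exchanged split of all arrays called 29 probe sets where the labelled one called 0. These arrays were singled out for their p53 targets, so that count is no separate support. The irradiated array of replicate 2 was nearest to the 6 h control of replicate 1 (0.938). The 24 h control of replicate 2 was nearest to the irradiated 12 h array of replicate 2 (0.947), but so was the 6 h control of replicate 2 (0.930). Outside the p53 list the irradiated array of replicate 2 correlated best with the 24 h control of replicate 1 (0.246, and -0.02 with its labelled partner). The 24 h control of replicate 2 also correlated best with that array (0.175). A signature built without p53 targets set the irradiated 12 and 18 h arrays against the 6 h controls, so it mixes irradiation with time in culture. Irradiated minus control at 24 h was -0.31 in replicate 2 and 0.67 in replicate 1. Both lie within 2 SDs of a difference (0.89), an SD that rests partly on arrays used to make the signature, so this decides nothing. The 24 h controls of replicates 1 and 2 scored 1.06 and 1.10, and the irradiated 24 h arrays 1.72 and 0.78. The long-gene medians of both replicate 2 arrays, -0.05 (irradiated) and -0.14 (control), lay above the -0.90 to -0.47 of the other irradiated arrays. The first is as in an exchange and the second is not. An exchange cannot be told apart from other causes with these few arrays.

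The G2/M and mitosis list differed between times by 0.44 in the same test, with irradiated minus control medians at 24 h of -0.29 in replicate 1 and 0.56 in replicate 2.

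Single arrays stood apart from their group in 11 of 210 checks, where about 10.5 are expected by chance, each measured as the gap to the nearest array divided by the range of the 8 irradiated or the 4 control arrays, which span several times. Among controls this ratio was 0.872 for CXCL12 in the 24 h array of replicate 2, 0.879 for RPL35 in the same array and 0.902 for the leukocyte list median, again in that array. In the 6 h control of replicate 2 it was 0.849 for CCNE1, 0.951 for MNAT1, 0.855 for SOX10 and 1 for NR4A1, whose other controls all lay at the floor. Among irradiated arrays it was 0.579 for CXCL12 in the 24 h array of replicate 2, 0.598 for JUNB and 0.633 for BIRC5 in the 24 h array of replicate 1, and 0.549 for the median of the recombination and checkpoint list in the 6 h array of replicate 2. Of 26 human control probe sets, 0 lay above all control arrays in all irradiated ones.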

How the results depend on the processing

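Chosen after the data were seen were the runs without both 24 h arrays of replicate 2 and most runs of the list tests. The number of probe sets called by limma was 0 in all 7 comparisons and stayed 0 under quantile normalization, median centring, the lower floor, the stricter filter and no intensity trend. Without a filter it was 16 at 6 h, 9 at 12 h, 26 at 18 h, 19 at 24 h, 1 over all times, 19 for the difference of effects and 28 between controls, all but 1 of the 18 h calls lying among dim probe sets that the filter removes. The higher floor called 2 over all times. The replicate numbers were not taken to pair the arrays, as same-numbered deviations correlated above 0.1 in only 7 of 15 pairs of groups, from -0.11 to 0.29, with 0.23 to 0.29 among both control groups and the irradiated 6 h group. Spike-in and maximum signals were higher in replicate 1 in all 6 groups. With the replicate block 1 probe set was called at 18 h. Leaving out both 24 h arrays of replicate 2 called 1 at 24 h, 13 over all times and 1 for the difference of effects. Leaving out each array in turn gave 0 to 0 at 6 h, 0 to 2 at 12 h, 0 to 3 at 18 h, 0 to 2 at 24 h, 0 to 4 over all times, 0 to 1 for the difference of effects and 0 to 0 between controls. The cause was not tested.

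The number of gene lists called was 0 in every comparison with an estimated correlation and with fry. It became 4 at 6 h, 7 at 12 h, 0 at 24 h and 5 between controls under quantile normalization, 4 at 6 h with the higher floor, 5 at 6 h, 4 at 18 h and 2 at 24 h without a filter, and 4 at 6 h and 5 over all times with the stricter filter. It was 5 at 6 h with the replicate block, where G2/M and mitosis, TGF-beta and heat shock passed (0.0486 each), 2 at 24 h against all 4 controls, and 7 at 12 h and 4 at 18 h against the 6 h controls alone. Without both 24 h arrays of replicate 2 it was 4 at 24 h, 7 over all times and 0 for the difference of effects. Over single arrays left out it ran from 2 to 4 at 6 h, 3 to 5 at 12 h, 1 to 6 at 18 h, 0 to 3 at 24 h, 2 to 6 over all times, 0 to 4 for the difference of effects and 1 to 8 between controls.

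For the p53 target list the adjusted p with an estimated correlation and with fry was 0.451 and 0.290 at 6 h, 0.551 and 0.302 at 12 h, 0.303 and 0.352 at 18 h, 0.476 and 0.281 over all times, 0.707 and 0.695 for the difference of effects and 0.533 and 0.595 between controls. At 24 h it was 0.0222 against all 4 controls and 5.21e-05 without both replicate 2 arrays, which gave 0.813 for the difference of effects. Over single arrays left out it ran from 2.00e-11 to 9.37e-04 at 6 h, 1.18e-09 to 2.18e-05 at 12 h, 1.08e-10 to 2.26e-04 at 18 h, 0.00723 to 0.533 at 24 h, 2.18e-13 to 2.01e-06 over all times, 3.15e-09 to 0.194 for the difference of effects and 6.24e-06 to 0.596 between controls. At 24 h the direction was reversed without the control of replicate 1 (0.533) and without the irradiated array of replicate 1 (0.203). In the same runs CDKN1A stood at -0.52 and -0.43 and GDF15 at -0.26 and -0.82. Over single arrays left out CDKN1A reached 1.08 at 24 h without the control of replicate 2, and GDF15 2.03 without the irradiated array of replicate 2. Of the other values of named genes, 1910 kept direction and side of the threshold and 11 became calls. Since no probe set passed in the main setting, no call could be lost. Many of these genes were also chosen by their p on the same arrays, so the count is no measure of robustness. The replicate block changed no other call. Where an array is left out of a group of 2, the remaining array is assumed to vary like the other groups. Signals near the floor limit what the dim genes can show.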

Other observations

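The test of RNA degradation at 18 h and the count of splits by unadjusted p were chosen after the result was seen. The other tests were set out before their own results, though the long-gene and replicate patterns they address came from these same arrays. The list of long genes was written from general knowledge after the first results and leaves out the genes with the smallest p. Of 141 genes listed as spanning very long stretches of the genome, 56 were measured, and 50 of these lay below 0 at 6 h with a median log2 change of -0.66. Examples at 6 h were NAV3 (-1.86), XYLT1 (-1.61), CDK14 (-1.52) and the cadherin gene CDH11 (-0.79). The median was -0.60 at 12 h with 52 of 56 below 0, -0.59 at 18 h with 47 below 0 and -0.18 at 24 h with 38 below 0. The 24 h effect minus the 6 h effect was 0.54, and untreated cells at 24 h stood at -0.22 against those at 6 h. Among 10000 random lists matched on mean signal these medians lay at percentile 0 at 6, 12 and 18 h and over all times, at 2.97 at 24 h, and at 0.02 between the untreated cells, which no irradiation separates. With an estimated correlation the camera p was 0.0544 at 6 h, 0.0383 at 12 h, 0.0494 at 18 h, 0.607 at 24 h and 0.0254 over all times, unadjusted, and 15 members had an unadjusted p under 0.05 over all times, all of them lower.

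For this pattern, low signal is argued against by the 20 members with a mean signal of at least 100, whose 6 h median of -0.53 lay at percentile 0 of their own random lists. Scaling is argued against by quantile normalization, after which the percentile was again 0. Between the untreated cells the percentile was 1.04 for the bright members and 0.03 after quantile normalization, so these runs do not single out irradiation. The percentiles also take genes as independent. RNA degradation is argued against at 6 and 12 h by the log2 3' to 5' ratio of GAPDH, which differed by 0.0273 and 0.0167 against a within-group SD of 0.107, but stays open at 18 h, where GAPDH differed by 0.309 and actin by 0.364 (SD 0.214). What also stays open is that UV lesions may lower the output of long genes, where a polymerase is more likely to meet one, and the per-array list medians were -0.59 ± 0.26 (SD, n = 8) in irradiated and -0.09 ± 0.20 (SD, n = 4) in control arrays with a two-sided exact permutation p = 0.0121. Gene length itself was not measured, and the hypothesis was formed and tested on the same arrays.

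The labelled replicates were not the most alike arrays. Among all 720 ways to match the replicate 1 arrays to the replicate 2 arrays on genes outside the p53 list, the labelled matching ranked 180, with a mean correlation of 0.057 against 0.32 for the best. This goes with a changed order of time labels in 1 of the replicates as a possible explanation. At 24 h the best matching also crossed the treatment labels. It paired the control of replicate 1 with the irradiated array of replicate 2 (0.246). The irradiated array of replicate 1 went with the control of replicate 2 (0.151). The labelled pairs gave 0.175 for controls and -0.02 for irradiated arrays. Taken alone, the irradiated 24 h array of replicate 1 correlated best with the irradiated 12 h array of replicate 2 (0.187). The 4 irradiated times alone gave rank 15 of 24. Differences between times that are small beside the spread between arrays would give the same rank, so this too stays open. The spike-in controls also differed between replicates, by 1.07 on the log2 scale higher in replicate 1.

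For the comparison over all times, the real split of the 12 arrays into 8 and 4 gave 0 probe sets past the threshold, so that all 100 of 100 splits necessarily gave as many and the count decides nothing. The highest other gave 29. That split takes the irradiated 24 h array of replicate 2 as a control in place of the 24 h control of replicate 2. This pair had already been singled out for its p53 targets, so the count is no separate evidence of an exchange. With an unadjusted p under 0.05, 17 of the 100 splits gave as many as the real 575, the highest other giving 941, so chance cannot be excluded for that number. For the p53 target list at the preset correlation 3 of the 100 splits, the real one included, gave a camera p as small as the real 1.90e-10, the smallest other being 2.87e-18 in the same exchanged split. That count covers this list alone and is not adjusted over the lists. The exact permutation of the list medians gave an adjusted p = 0.384, so chance cannot be excluded.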
